A study of Mus musculus with 11 samples.

How the data were processed

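Polyadenylated RNA was taken from cortex and hippocampus of NEX-RiboTag mice, either after immunoprecipitation of GFP-tagged ribosomes (3 libraries each at P7, P14 and P21) or from whole tissue (2 libraries at P7), and sequenced, per the labels' protocols. The authors deposited 1 table of TPM values with 77179 Ensembl gene IDs and 1 column for each of the 11 libraries. Per the submitters' processing notes, fastp 1.0.1, Salmon 1.10.0, DESeq2 1.46.0 and genome build mm39 were used; which step each served, the annotation release, how transcripts were summed to genes and whether strand was used are not given in the sources used here. TPM divides by transcript length and by the library's total, so a few abundant genes that change share shift all others, and the values keep no depth: the depth is unknown, and the precision of each value is given only by the spread between replicates.

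Symbols came from a table of Ensembl IDs and matched 50886 IDs, and 2492 of the tested genes had none. A RefSeq table of assembly GRCm38.p6, a different build from that of the deposited values, was used only for 9 older symbols of ATP synthase genes and for the genomic span of genes, and no coordinates are given. Columns were assigned to samples by name, and all were used.

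Genes with at least 1 TPM in at least 2 libraries were tested, 19008 in all. Values were log2-transformed with a pseudocount of 1 TPM and fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 11 libraries (7 residual degrees of freedom), empirical Bayes moderation with a trend, and Benjamini-Hochberg adjustment over genes; calls are at adjusted p below 0.05. The comparisons were P7 IP minus P7 input, P14 minus P7, P21 minus P14 and P21 minus P7 IP, a moderated F test over the 3 ages, and the second weekly step minus the first. The age comparisons share libraries, so their results are not independent of each other. The input group combines a Cre-positive and a Cre-negative library, and each was left out in turn.

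Before the data were examined, 32 gene lists were written from general knowledge: cell type markers, cortical layer and hippocampal genes, immature neuron, axon guidance, synaptic, receptor, channel, immediate-early, ribosomal protein, translation factor, oxidative phosphorylation, mitochondrially encoded, noncoding RNA, cholesterol, stress and extracellular matrix genes. They hold 775 entries and 752 distinct genes, so some genes stand in more than 1 list, and 8 entries were not tested. Each list was tested in the 4 pairwise comparisons with camera at a preset correlation of 0.01, adjusted over all 128 tests, beside camera with an estimated correlation and fry. Camera compares a list with other genes, and fry asks whether the members move, on balance, one way.

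Genes were named by a rule fixed at the same time. Neurod6, Rpl10a, Slc17a7, Gad1, Gfap, Mbp and Cx3cr1 are always eligible. In each pairwise comparison so are the 8 genes with the largest rise and the 8 with the largest fall among those with adjusted p below 0.05, a mean of at least 10 TPM in the higher group, no overlap between the groups' libraries and no predicted, clone-based or pseudogene symbol, and up to 4 members of each list, the 2 with the largest rise and the 2 with the largest fall. Other genes are said to have been chosen after their values were seen. Some results are not reported here.

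The code was tested on simulated data built on the 19008 genes with 66 or 67 genes changed at each of 3 sizes. Changed genes were drawn from those with a fitted P7 IP level above 5 TPM, and noise was independent between genes. Far fewer genes changed than were called in the data. The rates below therefore need not hold for genes of low TPM or for the data themselves. At a log2 change of 1 it recovered 97.0% of changed genes for IP against input, 91.0% for P14 against P7, 97.0% for P21 against P14 and 97.0% for P21 against P7, and at 0.5 it recovered 58.2%, 70.1%, 62.7% and 65.7%. Of all calls 5.08%, 4.40%, 3.35% and 2.78% were false, and 6.38% for the test over the 3 ages and 2.15% for unequal steps.

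The alternatives tried were pseudocounts of 0.1 and 5 TPM, no filter beyond a value above 0, a mean of at least 5 TPM, median-of-ratios scaling, quantile normalisation, rescaling without mitochondrially encoded, haemoglobin and ribosomal protein genes, moderation without a trend, the replicate number as a block, only the groups compared in the fit, and each library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.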

Results

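RNA bound to tagged ribosomes of excitatory neurons was profiled in 9 libraries from the cortex and hippocampus of young mice, beside 2 libraries of whole-tissue RNA, and all 11 were analysed together. In these NEX-RiboTag animals, Cre recombinase driven from the Neurod6 (NEX) locus switches on a GFP-tagged copy of the ribosomal protein Rpl10a in forebrain excitatory neurons. Beads carrying antibodies against GFP pull down the tagged ribosomes with their mRNA. The pull-down (IP) was sequenced at postnatal days 7, 14 and 21 (P7, P14 and P21), with 3 libraries per age that the labels call biological replicates. At P7 whole-tissue RNA (input) was sequenced in 2 libraries, replicate 1 from a Cre-positive and replicate 2 from a Cre-negative genotype. Values were TPM (transcripts scaled to a fixed total per library), which keep no record of sequencing depth, so the depth of each library is unknown and no counting interval is given. Between 15154 and 17793 genes reached 1 TPM in a library. Across genes, Pearson correlations of log2 values ranged from 0.988 to 0.994 within groups and from 0.927 to 0.933 between P7 IP and P7 input. The first principal component held 54.1% of the variance and the second 28.5%. Log2 changes below are on the log2(TPM + 1) scale, which understates changes of genes with low values, and their errors are standard errors of the limma fit. Adjusted p-values are from limma for genes and from camera for gene lists.

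The comparison of IP with input at P7 asked which transcripts the pull-down enriches or depletes relative to the tissue. Markers of cells other than excitatory neurons were far lower in the IP. Gad1 (ENSMUSG00000070880), which encodes a GABA-synthesising enzyme of inhibitory neurons, was at 6.27 TPM ± 1.68 (SD, n = 3) in IP and 69.6 TPM ± 2.22 (SD, n = 2) in input, a log2 change of -3.31 ± 0.18 (limma adjusted p = 1.22e-07). The astrocyte filament gene Gfap (ENSMUSG00000020932) changed by -3.82 ± 0.20, the myelin gene Mbp (ENSMUSG00000041607) by -2.53 ± 0.20 and the microglial receptor gene Cx3cr1 (ENSMUSG00000052336) by -2.97 ± 0.15. Of the inhibitory neuron markers 24 of 25 were lower and none was higher, with a median log2 change of -2.44. Among them the neuropeptide gene Sst was at 32.2 TPM in IP against 497 TPM in input and the vesicular GABA transporter gene Slc32a1 at 3.27 against 52.4 TPM. All 22 astrocyte markers were lower (median -2.92), with Apoe at 114 TPM against 2552 TPM and Aldoc at 11.1 against 206 TPM. All 20 microglia markers (median -2.92), all 15 oligodendrocyte precursor markers (median -2.18), 15 of 20 oligodendrocyte markers (median -1.27) and 16 of 17 endothelial markers (median -2.12) were lower. So were 16 of 16 markers of mural cells and fibroblasts (median -2.41), 11 of 12 radial glia markers (median -2.18) and 18 of 18 proliferation genes (median -1.59). The oligodendrocyte marker Tspan2 was higher by 0.40 ± 0.16. The complement genes C1qc and C1qb of microglia, the oligodendrocyte precursor gene Pdgfra and the endothelial junction gene Cldn5 stood at 1.41, 1.66, 1.84 and 10.4 TPM in IP and at 34.7, 35.2, 22.2 and 93.5 TPM in input. Adjusted over the list alone, 16 oligodendrocyte markers were lower, and the counts of the other lists stayed as given. Each of these lists was lower than other genes (camera adjusted p from 1.17e-08 for astrocytes to 0.0204 for oligodendrocytes). None of these calls held with an estimated correlation between members (adjusted p = 0.346 to 0.676 with an estimated correlation). The oligodendrocyte call was lost with a pseudocount of 5 TPM (adjusted p = 0.0711). The call of Tspan2 (adjusted p = 0.049) was lost without input replicate 1 (adjusted p = 0.211) or 2 (adjusted p = 0.09) and without P7 IP replicate 2 (adjusted p = 0.108) or 3 (adjusted p = 0.13). It was also lost with a pseudocount of 0.1 TPM (adjusted p = 0.0533), no filter (adjusted p = 0.108), moderation without a trend (adjusted p = 0.0609) and without mitochondrial, haemoglobin and ribosomal protein genes (adjusted p = 0.146).

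Markers of excitatory neurons themselves did not move as a group. Of 28 such markers 9 were higher in IP and 9 lower, both over all genes and adjusted over the list alone, with a median log2 change of 0.01 and a mean of -0.01 (camera adjusted p = 0.0767; adjusted p = 0.666 with an estimated correlation). Among them the transcription factor gene Neurod2 (0.64 ± 0.06) and Mpped1 (0.66 ± 0.07) were higher, the transcription factor gene Bcl11b was lower (-0.70 ± 0.08), and the kinase gene Camk2a was lower by -0.66 ± 0.14. Neurod6 (ENSMUSG00000037984), the locus that carries Cre, was at 152 TPM ± 13.4 (SD, n = 3) in IP and 112 TPM ± 32.6 (SD, n = 2) in input, a log2 change of 0.47 ± 0.14 (limma adjusted p = 0.0118). Slc17a7 (ENSMUSG00000070570), the vesicular glutamate transporter of these neurons, was at 628 TPM ± 106 (SD, n = 3) in IP and 537 TPM ± 32.4 (SD, n = 2) in input, and its log2 change of 0.21 ± 0.12 did not pass (limma adjusted p = 0.124). These values depend on single libraries and on scaling. Neurod6 was at 89.1 TPM in the Cre-positive and 135 TPM in the Cre-negative input. The 2 inputs differ in genotype at this locus. In the same order they also differ in Xist (0.058 and 28.8 TPM) and Eif2s3y (59.2 and 0 TPM), genes chosen after their values were seen. Genotype and other differences between the 2 libraries therefore cannot be told apart in this gap. The change of Neurod6 was 0.76 against the Cre-positive input alone, the genotype of the IP libraries, and 0.17 against the Cre-negative input alone. After quantile normalisation the change of Neurod6 was 0.36 (adjusted p = 0.0764). It did not pass with only the groups compared in the fit (adjusted p = 0.061). Slc17a7 passed at 0.35 (adjusted p = 0.00253) without P7 IP replicate 1 and at 0.62 (adjusted p = 0.000814) with median-of-ratios scaling, under which Camk2a no longer passed (-0.25, adjusted p = 0.126) and 20 of the 28 markers were higher and 1 lower. The list as a whole passed under that scaling (adjusted p = 0.00276) and without P7 IP replicate 1 (adjusted p = 0.0309).

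Ribosomal protein mRNAs stood higher in the IP, and mitochondrially encoded mRNAs and several noncoding RNAs lower. Rpl10a (ENSMUSG00000037805), the tagged protein, was at 3638 TPM ± 240 (SD, n = 3) in IP, 996 TPM in the Cre-positive input and 487 TPM in the Cre-negative input, a log2 change of 2.38 ± 0.27 (limma adjusted p = 1.72e-05). Ribosomal protein genes were higher in 72 of 79 cases and lower in 1, Rpl12, with a median log2 change of 0.75 (camera adjusted p = 1.39e-27; adjusted p = 0.366 with an estimated correlation). Together they made up 12.0% to 12.7% of TPM in P7 IP and 6.42% to 6.71% in input. Selenow (ENSMUSG00000041571), which encodes a selenoprotein, had the largest rise among genes eligible for naming, from 2527 TPM ± 99.7 (SD, n = 2) to 19629 TPM ± 549 (SD, n = 3), followed by Lst1 (2.66 ± 0.14) and Rpl41 (2.53 ± 0.10). Nuclear-encoded genes of oxidative phosphorylation were higher in 36 of 59 cases and lower in 10, 37 and 10 adjusted over the list alone, with a median of 0.29 (camera adjusted p = 4.26e-09; adjusted p = 0.346 with an estimated correlation). The call was lost after quantile normalisation, with 22 higher and 22 lower (adjusted p = 0.896), but kept with median-of-ratios scaling, with 54 higher and 1 lower. All 13 mitochondrially encoded mRNAs were lower, by a median of -3.81 (camera adjusted p = 5.77e-07; adjusted p = 0.395 with an estimated correlation). Their share of TPM fell from 11.5% and 13.3% in the 2 input libraries to between 0.677% and 0.879% in P7 IP. The cytoplasmic noncoding RNA Bc1 (ENSMUSG00000115783) had the largest fall, from 932 TPM ± 142 (SD, n = 2) to 5.68 TPM ± 2.49 (SD, n = 3), with a log2 change of -7.19 ± 0.67 (limma adjusted p = 4.86e-06). Of 11 nuclear noncoding RNAs 8 were lower and 2 higher, with Malat1 at -4.05 ± 0.21, Meg3 at -3.32 ± 0.34 and Pantr1 at 1.47 ± 0.07. The list did not pass (camera adjusted p = 0.116), although it did with median-of-ratios scaling (adjusted p = 0.0165), quantile normalisation (adjusted p = 0.00648) and no filter (adjusted p = 0.0114). Ribosomal protein, mitochondrial and globin genes have near-identical copies in the genome. How reads were divided among copies is not given in the sources used here, so their single values are uncertain.

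Over all 19008 genes tested, 3541 were higher and 9718 lower in IP at adjusted p below 0.05, of which 756 and 3485 changed at least 2-fold. The median log2 change of all genes was -0.33, and the directions above are to be read against it. Median-of-ratios scaling shifted this median by 0.33 and gave 6250 higher and 6147 lower genes, and quantile normalisation shifted it by 0.36 and gave 6256 and 6025. The medians of the lists of other cell types given above and of mitochondrially encoded mRNA stayed below 0, and that of ribosomal protein genes above 0, under both.

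**Figure D1:**
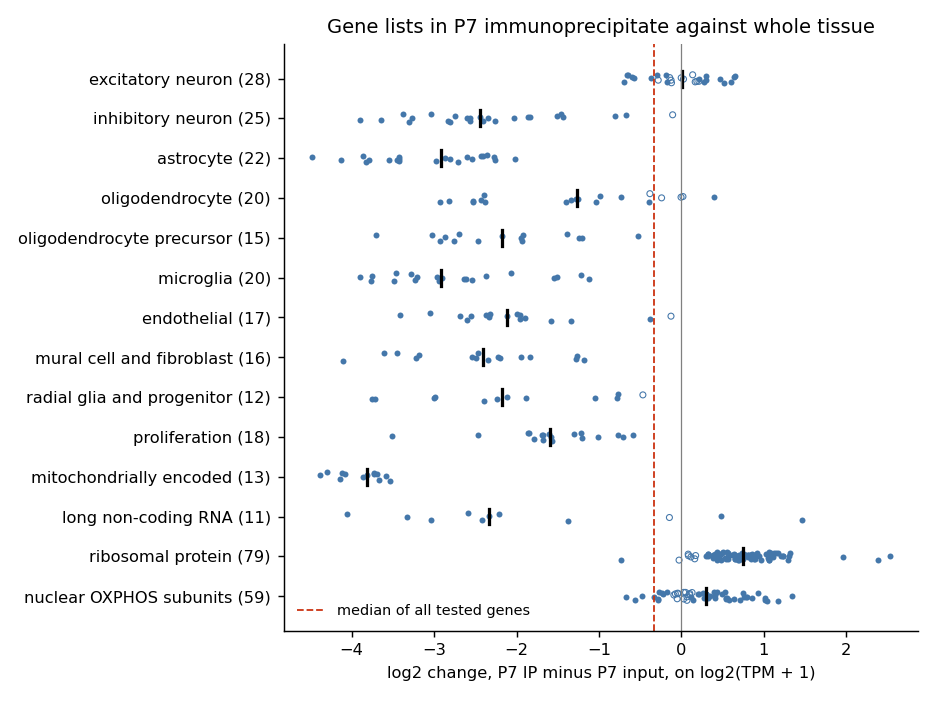
Log2 change of P7 IP over P7 input (horizontal axis, log2 of TPM + 1) for each tested member of selected gene lists (rows); filled points passed limma at adjusted p below 0.05, open points did not, black ticks mark list medians and the dashed red line the median of all 19008 genes, -0.33. Astrocyte and microglia markers lie around a median of -2.92, excitatory neuron markers around 0.01 and ribosomal protein genes around 0.75; the excitatory markers shift to mostly higher under median-of-ratios scaling.

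The comparison of P14 with P7 IP asked how the ribosome-bound RNA of these neurons changed over the second postnatal week. Genes of immature neurons fell together. Of 30 such genes 28 fell and none rose, with a median log2 change of -1.28, and adjusted over the list alone 28 fell and 1 rose (camera adjusted p = 1.25e-15; adjusted p = 0.346 with an estimated correlation). The tubulin gene Tubb2b (ENSMUSG00000045136) fell from 1846 TPM ± 159 (SD, n = 3) to 177 TPM ± 31.6 (SD, n = 3), a log2 change of -3.39 ± 0.13 (limma adjusted p = 1.47e-07), and Dpysl3, a regulator of growing axons, fell from 612 to 84.6 TPM. St8sia2, which adds polysialic acid to the adhesion molecule NCAM, fell from 22.1 to 1.45 TPM and Trim67 from 37.7 to 2.14 TPM. Of 24 cholesterol synthesis genes 21 fell and Ebp rose (median -0.82, camera adjusted p = 1.59e-10; adjusted p = 0.35 with an estimated correlation). The farnesyl diphosphate synthase gene Fdps fell from 234 to 65.7 TPM and Mvd from 67.4 to 23.1 TPM. Ribosomal protein genes fell in 68 of 79 cases, 69 adjusted over the list alone, by a median of -0.44, and Rps12 rose (camera adjusted p = 5.79e-14; adjusted p = 0.401 with an estimated correlation).

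Synaptic and excitability genes rose over the same week. Slc17a7 rose from 628 TPM ± 106 to 1823 TPM ± 88.2 (SD, n = 3 each), a log2 change of 1.55 ± 0.10 (limma adjusted p = 1.18e-06), while Neurod6 fell from 152 TPM ± 13.4 to 94.8 TPM ± 1.83 (log2 change -0.68 ± 0.12, adjusted p = 0.0011). Of 36 postsynaptic density genes 29 rose and 1 fell (median 0.75, 30 and 1 adjusted over the list alone), including the AMPA receptor auxiliary subunit gene Cacng3, from 52.2 to 227 TPM, and the scaffold gene Dlg1, from 11.3 to 43.4 TPM. Of 40 presynaptic genes 34 rose and 2, Rab3b and Syt4, fell (median 0.75). Of 42 voltage-gated channel genes 33 rose and 2 fell (median 0.46, 35 and 2 adjusted over the list alone), with the sodium channel subunit gene Scn2b going from 23.1 to 90.3 TPM. Of 25 immediate-early genes, which neuronal activity induces, 20 rose and 2 fell (median 1.14), with Arc going from 4.37 TPM ± 1.35 to 50.8 TPM ± 9.29 and Egr1 from 13.5 to 100.3 TPM. Of 16 GABA receptor and chloride transporter genes 10 rose and 1, Gabra5, fell (median 0.37), with Gabrd going from 6.01 to 24.6 TPM. Camera adjusted p-values of these 5 lists ran from 7.49e-11 for presynaptic to 0.00398 for GABA receptor genes, and none held with an estimated correlation (adjusted p = 0.346 to 0.495 with an estimated correlation). Of 28 excitatory neuron markers 12 rose and 11 fell, with Camk2a rising from 183 to 620 TPM, and the list did not pass (median -0.08, mean 0.29, adjusted p = 0.697). Lamp5 (ENSMUSG00000027270), an upper-layer marker in the fixed lists, rose from 16.02 TPM ± 2.74 to 249 TPM ± 48.7. Most of its list went the other way, with 4 of 15 genes rising and 9 falling (median -0.38, mean 0.12). The upper-layer list did not pass (camera adjusted p = 0.13), but was called down with no filter (camera adjusted p = 0.0299) and with fry (fry adjusted p = 0.0372).

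Genes of several glial cell types and of mitochondria were also higher at P14. The myelin gene Mobp (ENSMUSG00000032517) had the largest rise among genes eligible for naming, from 0.622 TPM ± 0.341 to 48.8 TPM ± 7.99 (SD, n = 3 each), a log2 change of 4.95 ± 0.22 (limma adjusted p = 2.09e-07). Mbp rose from 17.6 to 161 TPM. Of 20 oligodendrocyte markers 15 rose and 1, Tspan2, fell (median 0.92, camera adjusted p = 1.39e-05). Of 22 astrocyte markers 19 rose, 20 adjusted over the list alone (median 0.75, camera adjusted p = 6.9e-07), S100b from 2.05 to 14.3 TPM. Of 20 microglia markers 16 rose and 1 fell, 17 and 1 adjusted over the list alone (median 0.76, camera adjusted p = 0.000343), Cd68 from 3.80 to 12.8 TPM, and the list did not pass with genes of a mean of at least 5 TPM (adjusted p = 0.0946). Of 15 oligodendrocyte precursor markers 7 rose and 3 fell, and that list did not pass (median 0.31, camera adjusted p = 0.255). Of 25 inhibitory neuron markers 5 rose and 6 fell (median -0.06, mean 0.05, adjusted p = 0.76), Pvalb rising from 0.118 to 3.46 TPM and Npy falling from 36.0 to 20.6 TPM. All 13 mitochondrially encoded mRNAs rose by a median of 1.45 (camera adjusted p = 1.08e-07), to 2.03% to 2.35% of TPM. Of nuclear oxidative phosphorylation genes 38 of 59 rose and none fell, 40 and none adjusted over the list alone (median 0.22, camera adjusted p = 8.59e-07). With an estimated correlation none of these calls held (adjusted p = 0.366 to 0.554 with an estimated correlation). Gad1 rose by 0.47 ± 0.16 (limma adjusted p = 0.0302), a call lost without P7 IP replicate 1 (adjusted p = 0.0723) or 3 (0.31, adjusted p = 0.107) and without P14 IP replicate 1 (adjusted p = 0.0804) or 2 (adjusted p = 0.0775), with no filter (adjusted p = 0.0896) and with only the groups compared (adjusted p = 0.059). Gfap did not pass (0.44 ± 0.18, adjusted p = 0.0586) but did without P7 IP replicate 2 (0.62, adjusted p = 0.0103) or P14 IP replicate 3 (0.54, adjusted p = 0.0424), and with a mean of at least 5 TPM (adjusted p = 0.0403). Cx3cr1 rose by 0.74 ± 0.13 (adjusted p = 0.000979), and Rpl10a did not pass (-0.06 ± 0.24, adjusted p = 0.866). In all, 5073 genes rose and 4341 fell, of which 833 and 634 changed at least 2-fold. The larger number turned with scaling, to 4615 that rose and 4855 that fell with median-of-ratios scaling and to 4644 and 4848 after quantile normalisation. The 1467 genes of at least 2-fold became 2550 with a pseudocount of 0.1 TPM and 636 with 5 TPM.

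The comparison of P21 with P14 IP asked the same of the third week. Igfbp6 (ENSMUSG00000023046), which encodes an insulin-like growth factor binding protein, rose from 7.62 TPM ± 2.25 to 68.6 TPM ± 8.80 (SD, n = 3 each), a log2 change of 3.04 ± 0.17 (limma adjusted p = 6.09e-06). Stac2 rose from 19.6 to 81.4 TPM, Tnnc1 from 31.0 to 121 TPM and Hapln4, a link protein of the extracellular matrix around neurons, from 6.10 to 26.9 TPM. Immature neuron genes fell further, 21 of 30 with none rising, 24 adjusted over the list alone (median -0.68, camera adjusted p = 1.51e-11; adjusted p = 0.364 with an estimated correlation). Dpysl5 went from 61.3 to 11.4 TPM and Dpysl3 from 84.6 to 16.1 TPM. Of 24 cholesterol synthesis genes 17 fell and none rose, 19 and 1 adjusted over the list alone (median -0.36, camera adjusted p = 8.00e-06; adjusted p = 0.395 with an estimated correlation). Sqle went from 56.8 to 34.3 TPM. Of 36 axon guidance genes 16 fell and none rose, 17 adjusted over the list alone (median -0.26, camera adjusted p = 4.23e-05; adjusted p = 0.39 with an estimated correlation). The ephrin gene Efnb3 went from 128 to 56.6 TPM. Immediate-early genes rose in 9 of 25 cases and 1, Nr4a3, fell, 11 and 1 adjusted over the list alone (median 0.28, camera adjusted p = 6.69e-05; adjusted p = 0.39 with an estimated correlation). Nptx2 went from 45.2 to 87.2 TPM.

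Postsynaptic density, presynaptic and channel genes went both ways in this week. Of 36 postsynaptic density genes 11 rose and 11 fell, 13 and 11 adjusted over the list alone, with the dendritic gene Ddn rising from 512 to 1098 TPM and the scaffold gene Dlg2 falling from 154 to 112 TPM. Of 40 presynaptic genes 7 rose and 6 fell, Vamp1 rising from 15.6 to 28.2 TPM and Rab3b falling from 76.8 to 38.2 TPM. Of 42 voltage-gated channel genes 9 rose and 10 fell, 9 and 13 adjusted over the list alone, with the sodium channel subunit gene Scn4b rising from 3.75 to 10.0 TPM. These lists did not pass (camera adjusted p = 0.139, 0.174 and 0.296), although the first and second did with median-of-ratios scaling (adjusted p = 0.0497 and 0.0341). Of 24 glutamate receptor genes 6 fell and none rose, 5 adjusted over the list alone (median -0.17). That list did not pass (camera adjusted p = 0.15) but did with no filter (camera adjusted p = 0.00349) and with fry (fry adjusted p = 0.00816). Of 16 GABA receptor and chloride transporter genes 2 rose and 5 fell (median -0.09, camera adjusted p = 0.904). Oligodendrocyte markers rose in 15 of 20 cases and none fell (median 0.83, camera adjusted p = 7.49e-11; adjusted p = 0.366 with an estimated correlation), Trf from 3.64 to 15.2 TPM and Mal from 7.17 to 26.2 TPM. Astrocyte markers rose in 6 of 22 cases (median 0.08, camera adjusted p = 0.00164; adjusted p = 0.601 with an estimated correlation and 0.189 with fry). The erythroid list was also called up, with 3 of 5 genes rising (median 0.97, adjusted p = 0.00582; adjusted p = 0.469 with an estimated correlation and 0.0637 with fry). So were, with few members rising and none falling, endothelial (3 of 17, adjusted p = 0.014), microglia (2 of 20, adjusted p = 0.019) and choroid plexus and ependymal markers (1 of 10, adjusted p = 0.0327). With an estimated correlation none of the 3 held (adjusted p = 0.584, 0.692 and 0.366 with an estimated correlation). Fry called the choroid plexus and ependymal list (fry adjusted p = 0.0142) but not the endothelial (0.159) or microglia list (0.428). Single libraries ended each call: that of endothelial markers was lost without P21 IP replicate 3 (adjusted p = 0.0976) and with a mean of at least 5 TPM (adjusted p = 0.242). The microglia call was lost without P14 IP replicate 3 (adjusted p = 0.115) or P21 IP replicate 2 (adjusted p = 0.105) and with median-of-ratios scaling (adjusted p = 0.0536). The choroid plexus and ependymal call was lost without P14 IP replicate 2 (adjusted p = 0.0545) or P21 IP replicate 2 (adjusted p = 0.0562) and with median-of-ratios scaling (adjusted p = 0.0682). Of 25 inhibitory neuron markers 4 rose and 7 fell (median -0.06, adjusted p = 0.796), Pvalb rising from 3.46 TPM ± 0.485 to 13.8 TPM ± 1.44 and Calb2 falling from 37.1 to 19.1 TPM. Of 15 oligodendrocyte precursor markers 4 fell and none rose (median -0.12, camera adjusted p = 0.557). Nuclear oxidative phosphorylation genes rose in 25 of 59 cases and fell in 3 (median 0.13, camera adjusted p = 4.35e-09; adjusted p = 0.346 with an estimated correlation). Of 13 mitochondrially encoded mRNAs 3 rose and 1 fell, at 1.96% to 2.67% of TPM, and the list did not pass (adjusted p = 0.182) except without P21 IP replicate 1 (adjusted p = 0.0192). Ribosomal protein genes rose in 6 and fell in 8 of 79 cases (median 0.01, camera adjusted p = 0.0849), a list that passed without P21 IP replicate 1 (adjusted p = 4.77e-05) or P14 IP replicate 3 (adjusted p = 0.0158), with median-of-ratios scaling (adjusted p = 0.00276) and with a mean of at least 5 TPM (adjusted p = 0.0295). Mbp rose by 0.65 ± 0.18 (limma adjusted p = 0.0236), a call lost without P14 IP replicate 3 (0.49, adjusted p = 0.0871), P21 IP replicate 2 (adjusted p = 0.0823) or P21 IP replicate 3 (adjusted p = 0.0763) and with no filter (adjusted p = 0.0834). Slc17a7, Gad1, Gfap, Cx3cr1, Rpl10a and Neurod6 did not pass, with log2 changes of 0.17, 0.23, 0.33, -0.02, -0.27 and -0.35. Of these Neurod6 passed with a mean of at least 5 TPM (adjusted p = 0.0402) and with only the groups compared (adjusted p = 0.00483). In all, 1621 genes rose and 3749 fell, of which 141 and 126 changed at least 2-fold. This split moved with scaling, to 2732 and 2273 with median-of-ratios scaling and to 2290 and 2662 after quantile normalisation. The 267 genes of at least 2-fold became 729 with a pseudocount of 0.1 TPM and 79 with 5 TPM.

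**Figure D2:**
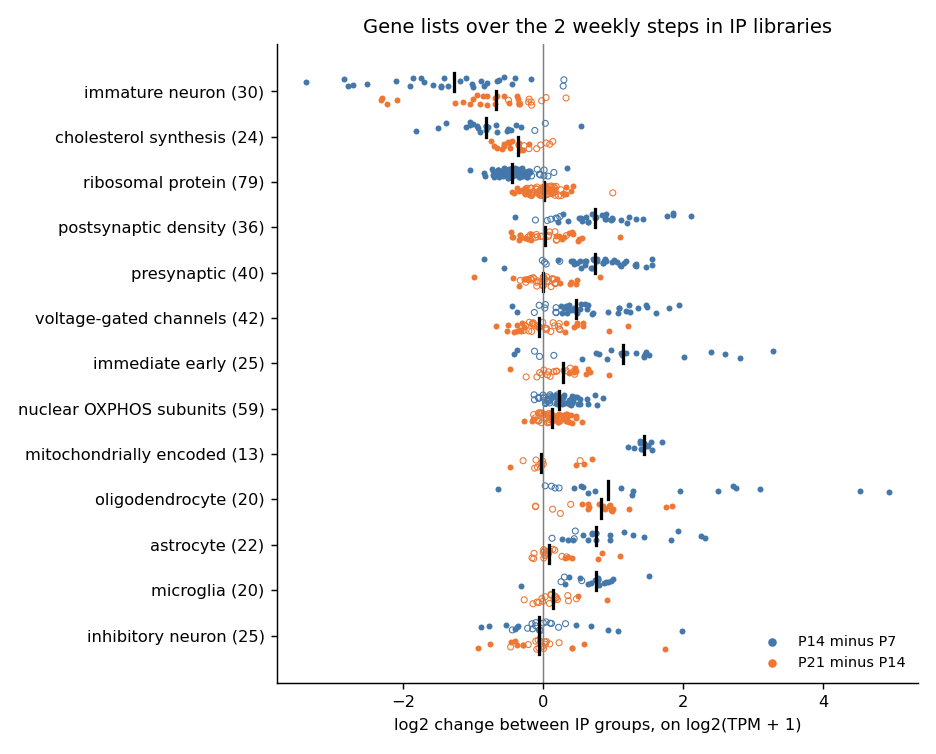
Log2 change per list member (horizontal axis, log2 of TPM + 1) from P7 to P14 and from P14 to P21 IP; filled points passed limma at adjusted p below 0.05, open points did not, and black ticks mark list medians. The immature neuron median is -1.28 in the first step and -0.68 in the second, and the postsynaptic density median is 0.75 and then 0.03.

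Across both weeks, from P7 to P21, the same libraries gave 5180 genes that rose and 6204 that fell, of which 1358 and 1422 changed at least 2-fold. The larger number turned with median-of-ratios scaling, where 5808 rose and 5672 fell, but not after quantile normalisation, with 5535 and 5929. Tubb2b fell from 1846 to 40.2 TPM, the microtubule gene Dcx of migrating neurons from 66.8 to 3.29 TPM and Cd24a from 1061 to 31.7 TPM. Of immature neuron genes 27 of 30 fell, 28 adjusted over the list alone (median -1.93, camera adjusted p = 2.19e-13; adjusted p = 0.346 with an estimated correlation). Igfbp6 rose from 0.644 to 68.6 TPM, Lamp5 from 16.02 to 388 TPM and Arc from 4.37 to 79.4 TPM. Mobp rose from 0.622 to 96.0 TPM. Of oligodendrocyte markers 18 of 20 rose and 1 fell, of astrocyte markers 21 of 22 rose and none fell, and of microglia markers 18 of 20 rose and 1 fell, with medians of 1.58, 0.81 and 0.92. Their camera adjusted p-values were 4.13e-08, 9.62e-08 and 4.91e-05 (adjusted p = 0.39, 0.395 and 0.494 with an estimated correlation). Slc17a7 rose by 1.72 ± 0.10 and Neurod6 fell to 74.4 TPM ± 3.85 (log2 change -1.02 ± 0.12, limma adjusted p = 3.79e-05). Gad1 rose by 0.70 ± 0.16 (adjusted p = 0.00304), Gfap by 0.78 ± 0.17 (adjusted p = 0.00293), Mbp by 3.76 ± 0.18 and Cx3cr1 by 0.72 ± 0.13. Rpl10a did not pass, at 2972 TPM ± 715 in P21 IP (adjusted p = 0.272). Chn1os1 (ENSMUSG00000085838), which by its name overlaps Chn1 on the other strand, was listed at 0 TPM in all 3 P7 libraries and at a mean of 23.2 TPM at P14 and 47.1 TPM at P21. Whether strand was used in counting is not given in the sources used here, so reads of these overlapping genes cannot be told apart.

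**Figure D3:**
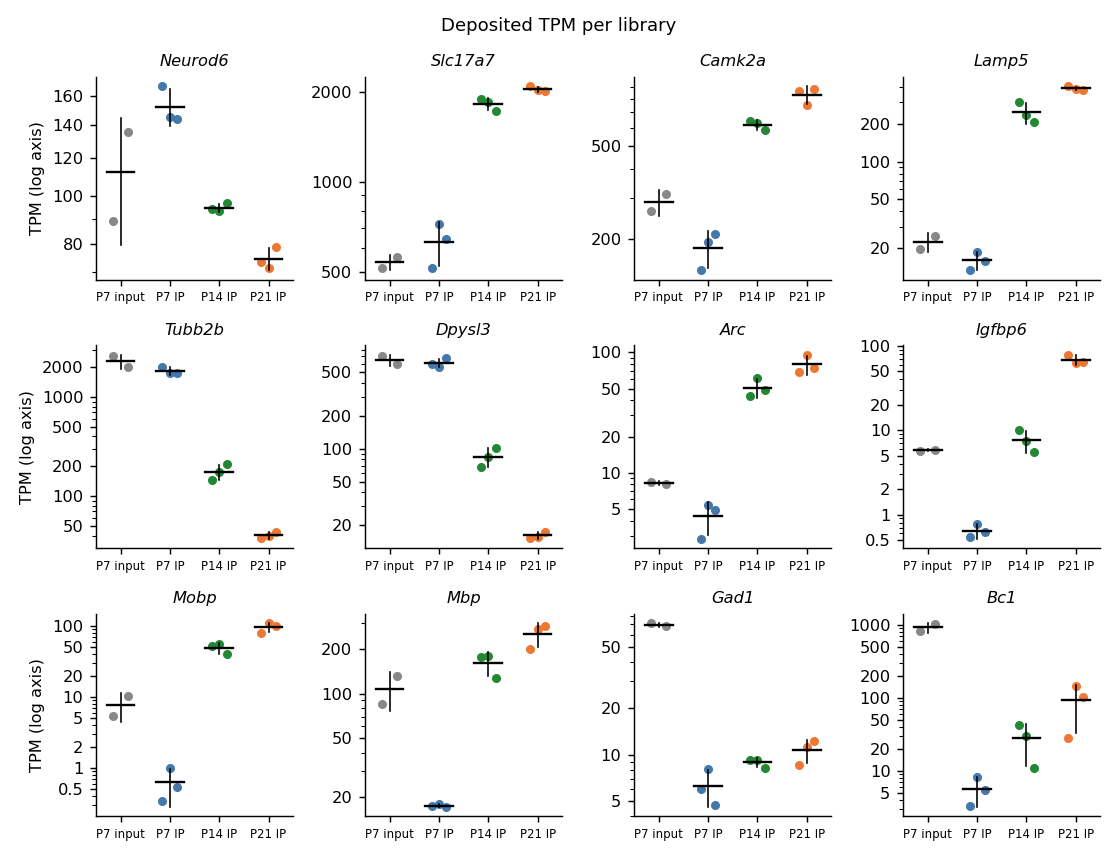
TPM of 12 genes in each library (points, log axis) by group, with the mean as a line and 1 SD as the bar. Tubb2b goes from 1846 to 177 to 40.2 TPM over P7, P14 and P21 IP, Arc from 4.37 to 50.8 to 79.4 TPM, and Gad1 is at 69.6 TPM in input and 6.27 TPM in P7 IP.

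A test of any change over the 3 ages called 11901 of 19008 genes. To compare the weeks, the difference between the second and the first step was tested itself and called 4613 genes. By the estimates, the first step was the larger in size in 3672 of them and the second in 937. The test compares signed steps, so where the signs are opposite a call does not show which step was larger. In 1863 of the genes with a larger first step the estimates of the 2 steps had opposite signs, whether or not each step was called, and over all genes 712 had both steps and their difference called with opposite signs. Among genes called over the 3 ages, the median absolute log2 change was 0.43 in the first step and 0.25 in the second. Without P14 IP replicate 2 the count of unequal steps was 3012. The difference was positive in 1418 genes and negative in 3195, a split that moved to 2247 and 2041 with median-of-ratios scaling and to 1976 and 2343 after quantile normalisation, which shifted the median difference of all genes by 0.13 and 0.11.

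**Figure D4:**
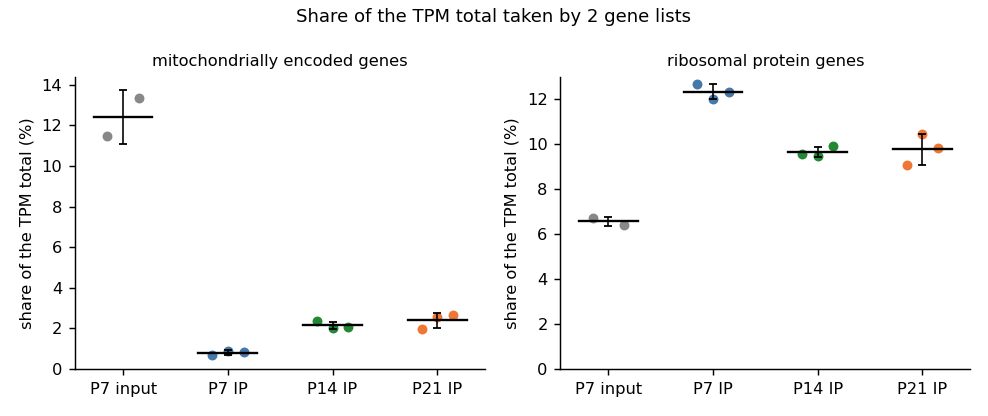
Share of TPM per library (vertical axis, percent) taken by mitochondrially encoded mRNA and by ribosomal protein genes, by group. Mitochondrially encoded mRNA takes 11.5% and 13.3% in the input libraries and at most 2.67% in any IP library, and ribosomal protein genes take 6.42% to 6.71% in input and 9.06% to 12.7% in IP.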

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

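Of the 228 genes named for the weekly steps 11 changed direction between the second and the third postnatal week, with both steps called in opposite directions and the difference between them tested and called in limma; the test of the difference was planned, and asking for opposite directions was chosen after the results were seen. The value given for each is the second step minus the first, on the log2 scale. The orphan receptor gene Gpr17 of oligodendrocyte precursors rose by 1.42 and then fell by 0.55, a difference of -1.97 (adjusted p = 0.000331). The mitochondrially encoded mt-Nd6 rose by 1.40 and fell by 0.47 (-1.87, adjusted p = 0.000381). The scaffold gene Dlg2 rose by 0.70 and fell by 0.46 (-1.16, adjusted p = 0.00188). The neuropeptide gene Npy went the other way, falling by 0.77 and then rising by 0.58 (1.35, adjusted p = 0.00284). In these 4 genes both steps and the difference passed in each of the 9 fits that left out 1 IP library, and with median-of-ratios scaling and quantile normalisation. The second step of mt-Nd6 did not pass with no filter (adjusted p = 0.0537) or with only the groups compared in the fit (adjusted p = 0.0549).

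The remaining genes all rose and then fell, with differences of -1.64 for Gpr6, -1.17 for Sv2c, -1.01 for the noncoding RNA Miat, -0.74 for Hopx, -0.71 for Sesn2, -0.70 for Dnajb9 and -0.34 for Atp5f1, an ATP synthase gene. The difference passed in each of the 9 fits for these genes except Hopx, where it was lost without P14 IP replicate 2 (-0.71, adjusted p = 0.0578). Both steps and the difference passed together in 7 of the 9 fits for Gpr6, 5 for Sv2c, 4 for Miat, 3 for Hopx, 5 for Sesn2, 5 for Dnajb9 and 8 for Atp5f1. The change of direction also depended on scaling. With median-of-ratios scaling the fall no longer passed for Atp5f1 (-0.04, adjusted p = 0.528), Dnajb9 (-0.13, adjusted p = 0.169), Hopx (-0.23, adjusted p = 0.128) and Sesn2 (-0.19, adjusted p = 0.0961), nor did the rise of Miat (0.30, adjusted p = 0.0687), and the difference was lost for Atp5f1 (adjusted p = 0.109). After quantile normalisation the fall was lost for Dnajb9 (adjusted p = 0.156), Hopx (adjusted p = 0.16) and Sesn2 (adjusted p = 0.0686), the rise for Miat (adjusted p = 0.0839) and the difference for Hopx (adjusted p = 0.0592). With no filter Dnajb9, Hopx and Miat each lost a step. Miat also lost its rise without mitochondrial, haemoglobin and ribosomal protein genes, without a trend in the moderation and with only the groups compared. Over all tested genes 712 met the same conditions, 605 of them rising and then falling and 107 falling and then rising, and 58 had a step of at least 2-fold. The lean to a rise before a fall was kept after quantile normalisation (337 rising first and 193 falling first) but not with median-of-ratios scaling (254 and 259). Both put the median change of all genes near 0 in the 2 steps. It was -0.004 and -0.01 after quantile normalisation and 0 and 0.011 with median-of-ratios scaling. No technical or biological explanation was tested for these genes.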

How the results depend on the processing

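All alternatives were planned before the data were examined. Of the 6 counts of called genes, those for P14 against P7, P21 against P14, P21 against P7 and the 3 ages stayed within 1.5 times of the reported value under each alternative. IP against input gave 8265 genes with a mean of at least 5 TPM, where 10856 genes were tested instead of 19008. With each library left out in turn, the counts ranged from 11733 to 12934 for IP against input (1 input library is then assumed to vary like the other groups), 8288 to 8813 for P14 against P7, 3813 to 5071 for P21 against P14, 10552 to 10898 for P21 against P7, and 11053 to 11672 for the 3 ages. For unequal steps they ranged from 3012 to 4698, the lowest without P14 IP replicate 2, which leaves fewer samples. Counts of genes changed at least 2-fold moved by over 1.5 times in 10 cases. With a pseudocount of 5 TPM they were 1629, 636, 79 and 1343 for IP against input, P14 against P7, P21 against P14 and P21 against P7 (4241, 1467, 267 and 2780 as reported), with 0.1 TPM 2550, 729 and 4274 for the 3 age comparisons, and with a mean of at least 5 TPM 2022, 162 and 1834 for all but P14 against P7. The median change of all genes for IP against input also shifted by 0.14 with a pseudocount of 5 TPM, 0.28 with no filter, 0.11 with a mean of at least 5 TPM and -0.11 without mitochondrial, haemoglobin and ribosomal protein genes.

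The replicate numbers paired the samples weakly at most across all genes. Of 15 correlations between same-numbered libraries 1 was over 0.1 (range -0.105 to 0.177), and 6 of 9 IP libraries correlated best with their own number. Replicate 3 had the highest Xist at P7, P14 and P21 IP (3.29, 3.38 and 6.02 TPM) and the lowest Eif2s3y (0.525, 0.182 and 0.205 TPM). The numbers thus tracked these 2 genes across ages. With the replicate block the counts were 13349, 9620, 5595, 11570, 12020 and 4866, in the order of comparisons above. Of 469 called results for single genes 38 lost their call without some library, and of 65 list calls 7 did. With an estimated correlation 0 of 65 list calls held (0.05 was not reached in any of 128 tests), whereas fry called 91 of 128.

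Where a named gene or a list passed under at least 1 of the 2 settings compared, its direction changed in 15 cases, which were for IP against input. With median-of-ratios scaling, which centres the genes' median at 0, the log2 change turned positive for Egfl7 (0.28), Ramp2 (0.028), Rsph1 (0.32), Grm8 (0.28), Grik5 (0.32) and Rpl32 (0.38), and after quantile normalisation for Gpr149 (0.40), Rsph1 (0.55), Grm8 (0.52) and Has3 (0.49). After quantile normalisation translation factor genes (adjusted p = 0.401) and nuclear oxidative phosphorylation genes (adjusted p = 0.896) leaned the other way. Under fry, which sets members against 0 and not against other genes, upper-layer (adjusted p = 0.00327), postsynaptic density (adjusted p = 0.0369) and translation factor genes (adjusted p = 0.923) did. Lists that passed under neither camera nor fry also differed in direction between them, in 7 tests of the age comparisons among others, and the larger of the numbers of rising and falling genes turned with scaling in the age comparisons too. The causes of the quantile results were not tested. Depth is unknown, so its limits on genes of low TPM cannot be stated.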

Other observations

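At P7, 19 of 24 glutamate receptor genes were lower in IP than in input and none higher (median -0.66, camera adjusted p = 0.00433; adjusted p = 0.469 with an estimated correlation), although 4 were higher and 16 lower with median-of-ratios scaling; the kainate receptor gene Grik1 was at 4.85 TPM against 16.3 TPM. Genes of the matrix net around neurons and of the brain matrix at large were lower in 11 of 13 cases (median -1.90, adjusted p = 0.00138; adjusted p = 0.39 with an estimated correlation), Sparc at 18.9 TPM against 267 TPM, and choroid plexus and ependymal markers in 9 of 10 (median -1.62, adjusted p = 0.00834; adjusted p = 0.346 with an estimated correlation). Ttr, of that list, was at 21.6 TPM against 516 TPM. Striatal neuron markers were lower in 10 of 13 cases (median -1.04, adjusted p = 0.0333; adjusted p = 0.395 with an estimated correlation), a call lost without input replicate 2 (adjusted p = 0.0701) and with a mean of at least 5 TPM (adjusted p = 0.0859). All 5 tested erythroid genes were lower (median -2.11, adjusted p = 0.144), a list that passed with median-of-ratios scaling (adjusted p = 0.0468), quantile normalisation (adjusted p = 0.0227) and no filter (adjusted p = 0.0109). Axon guidance genes were not called as a list (2 higher, 27 lower of 36, adjusted p = 0.0602). They were without P7 IP replicate 3 (adjusted p = 0.0372), with the replicate block (adjusted p = 0.035), with no filter (adjusted p = 0.000565) and without mitochondrial, haemoglobin and ribosomal protein genes (adjusted p = 0.0494). Voltage-gated channel genes were not called either (3 and 26 of 42, adjusted p = 0.113), but were without the same library (adjusted p = 0.0347) and with no filter (adjusted p = 0.00273). Also not called were presynaptic (2 and 22 of 40, adjusted p = 0.116), postsynaptic density (7 and 19 of 36, adjusted p = 0.787), and GABA receptor genes (1 and 9 of 16, adjusted p = 0.347). The same held for immediate-early (3 and 17 of 25, adjusted p = 0.328), immature neuron (9 and 10 of 30, adjusted p = 0.207), cholesterol synthesis (2 and 17 of 24, adjusted p = 0.231) and stress response genes (2 and 12 of 16, adjusted p = 0.139), and for upper-layer (3 and 7 of 15, adjusted p = 0.923), deep-layer (4 and 7 of 18, adjusted p = 0.343) and hippocampal markers (3 and 10 of 17, adjusted p = 0.78). Of these the presynaptic list passed after quantile normalisation (adjusted p = 1.68e-07), with no filter (adjusted p = 0.00381) and without mitochondrial, haemoglobin and ribosomal protein genes (adjusted p = 0.041). The cholesterol list passed after quantile normalisation (adjusted p = 0.00343) and with no filter (adjusted p = 0.0195), and the stress list with no filter (adjusted p = 0.00695). Of the lists not called in this paragraph, fry called all but the immature neuron and deep-layer lists. Translation factor genes were higher in 12 and lower in 11 of 32 cases (median 0.01, adjusted p = 0.0468; adjusted p = 0.435 with an estimated correlation), a call lost without input replicate 2 (adjusted p = 0.0838) or P7 IP replicate 1 (adjusted p = 0.0688). It was also lost with a pseudocount of 0.1 TPM (adjusted p = 0.0547), a mean of at least 5 TPM (adjusted p = 0.256), quantile normalisation (adjusted p = 0.401), the replicate block (adjusted p = 0.0529) and without mitochondrial, haemoglobin and ribosomal protein genes (adjusted p = 0.103).

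With age, hippocampal markers rose in 10 of 17 cases and fell in 2 from P7 to P14 (median 0.56, camera adjusted p = 0.00852; adjusted p = 0.548 with an estimated correlation), the calcium-binding protein gene Calb1 from 10.8 to 50.5 TPM. From P7 to P14 the deep-layer markers Pcp4 and Ntsr1 went from 1141 to 2787 TPM and from 18.3 to 6.88 TPM, in a list with 5 rises and 5 falls among 18 genes. Translation factor genes fell in 17 of 32 cases and rose in 4 from P7 to P14 (adjusted p = 0.00536; adjusted p = 0.39 with an estimated correlation), and 7 of 18 proliferation genes fell (adjusted p = 0.0117; adjusted p = 0.39 with an estimated correlation). Stress response genes rose in 11 of 16 cases from P7 to P21 and fell in 3 (median 0.62, adjusted p = 0.00622; adjusted p = 0.494 with an estimated correlation), with Atf4, a transcription factor of the stress response, falling from 197 to 132 TPM. Glutamate receptor genes included Grin2a, rising from 3.68 to 14.7 TPM between P7 and P21, and Grin3a, falling from 15.96 to 4.26 TPM. Bc1, chosen here after its values were seen, stood at 5.68 TPM, 27.8 TPM and 92.3 TPM in P7, P14 and P21 IP, and the immunoglobulin gene Ighm at 1.37 TPM, 19.5 TPM and 57.1 TPM. The labels give no sex of the animals. Xist and Eif2s3y, also chosen after their values were seen, differed between libraries. Xist was at 28.8 TPM in input replicate 2 and 3.29, 3.38 and 6.02 TPM in replicate 3 of P7, P14 and P21 IP. Eif2s3y was at no more than 0.525 TPM in these 4 libraries. In P21 IP replicate 1 Xist was at 0.646 TPM with Eif2s3y at 6.72 TPM.

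The tests of the 3 patterns below were chosen after the results were seen, and the splits of samples were planned. Oligodendrocyte, astrocyte and microglia genes were higher in IP at later ages. With unchanged tissue levels, an equal rise of RNA carried over from every other cell type is argued against by the lists moving apart. From P7 to P21 the oligodendrocyte median was 1.58 and the inhibitory neuron median -0.14, a difference of 1.71 (permutation test, p = 5e-05). If tissue levels changed with age, the lists could move apart under an equal rise of the carry-over too. With 0 input libraries at P14 or P21 that case cannot be judged. This pair was picked after the values were seen, but over all 55 pairs of the 11 lists of other cell types 27 passed, this one among them (permutation test, adjusted p = 0.00138). The permutations shuffled genes and took list members as independent. Their estimated correlation was 0.50 for oligodendrocyte and 0.17 for inhibitory neuron markers, so these p-values are likely too small. Other RNA lower in IP at P7 also rose from P7 to P21: erythroid genes in 5 of 5 cases (median 1.39, camera adjusted p = 0.0585), choroid plexus and ependymal markers in 6 of 10 with 1 fall (0.53, adjusted p = 0.0314; adjusted p = 0.366 with an estimated correlation), endothelial markers in 8 of 17 with 2 falls (0.21, adjusted p = 0.0767), all 13 mitochondrially encoded mRNAs (1.44) and Gad1 (0.70), while 11 of 18 proliferation genes fell. The remaining lists lower at P7 had medians of 0.385 for striatal neuron, 0.249 for oligodendrocyte precursor, 0.154 for mural and fibroblast and -0.018 for radial glia markers. The striatal neuron and precursor medians thus lay above the endothelial one. A rise of carry-over that differs between cell types therefore stays open, as does an equal rise while tissue levels change. More glia in the tissue at later ages with an unchanged carry-over cannot be told apart from a change in these neurons, since there were 0 input libraries at P14 or P21. A hypothesis is that the rise follows the growth of myelin and glia in the tissue at these ages, which stays untested.

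Ribosomal protein mRNAs were higher in IP than in input at P7. A trend with genomic span, which includes introns, is argued against as the whole cause. The list's median log2 change was 0.75 before and 0.82 after the median of genes of like span was taken away, at percentile 100 of 10000 random lists (span known for 91.9% of 16516 genes, all 79 of the list among them). Genes of like span did not share the rise, since medians of 8 groups by span ran from -0.52 to -0.002. Span is not transcript length, and a trend with transcript length was not tested. The share of mitochondrially encoded mRNA taken out of the total is also argued against as the whole cause. With TPM rescaled without these genes the median was 0.56 in place of 0.75, and 66 genes were called higher. This share can thus account for a part of the rise. Reads moved between these genes and their pseudogenes cannot be excluded: unnamed, predicted and pseudogene-named genes lost up to 39% of the share that ribosomal protein genes gained. No biological explanation was tested.

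Rpl10a had the second largest rise in IP among the 79 ribosomal protein genes, after Rpl41. Reads of the tagged Rpl10a transcript counted as Rpl10a may account for this, since its log2 ratio between the Cre-positive and the Cre-negative input library was 1.03, the highest of 79, with the others between -0.18 and 0.52. These are 1 library each, so the ratio has no test. The libraries also differ in Xist and Eif2s3y, as given above, so genotype is not the only difference between them.

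Other splits of the same libraries were fitted to see whether chance could be excluded. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In these 1 of 10 reached the real 9414 genes for P14 against P7 (highest other 1), 1 of 10 the real 5370 for P21 against P14 (highest other 2) and 1 of 10 the real 11384 for P21 against P7 (highest other 1). For the 3 ages 1 of 100 drawn splits reached the real 11901 (highest other 8902), the lowest share that 100 splits can give. In that highest other split 1 group held all 3 P7 libraries, so it carries differences between ages too. At a share under 0.05 chance can be excluded for the count as a whole, though not for single genes. For unequal steps 6 of 100 drawn splits reached the real 4613 (highest other 9860), so the count of splits does not exclude chance. In each of the other 5, 1 group held all 3 libraries of a single age, so these splits carry differences between ages. They point to that structure of the samples and are no measure of chance alone, and whether chance can be excluded stays open here.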
